A study of Mus musculus with 10 samples.

How the data were processed

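The series holds single-cell RNA-seq of myeloid cells sorted from bone marrow and lung of mice with KP lung tumours, and single-cell ATAC-seq. Of the 10 GEO samples, the 8 RNA samples (gene expression and multiplexing tags) were used, and the 2 ATAC samples were not analysed here. Per the labels' protocols, cells were labelled with multiplexing oligonucleotides, pooled and run on 10x Genomics 3' chemistry. The deposited values are UMI counts per gene and cell barcode in filtered matrices made by the authors with Cell Ranger on build mm10, per the submitters' processing notes. The Cell Ranger version is not given in the sources used here. Each matrix held 32285 genes and 12 tags. The 12 matrices, 3 pools for each of 2 genotypes in 2 tissues, came from 4 gene expression libraries, 1 per tissue and genotype. The tag of a matrix was the top tag of all its barcodes in 8 pools, and of 3410 of 3412 in marrow KO pool 1, 3327 of 3331 in marrow KO pool 3, 3215 of 3219 in lung WT pool 1 and 2328 of 2329 in lung WT pool 2. No pool was a copy of another of the same tissue and genotype, the only pairs compared.

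Cells with at least 300 genes, at least 500 UMIs and under 15% mitochondrial UMIs were kept. Doublets were called per pool with Scrublet in scanpy 1.11.5 (expected rate 6%, automatic threshold), and 718 calls were removed. The rule set before the data were examined was to remove none where under 0.5% of cells were called. This was not applied to lung WT pool 2, whose 6 calls (0.342% of cells) were removed as well. A setting with all calls kept was run. Calls made up 2.55% of WT and 2.5% of KO marrow cells, and 0.559% of WT and 1.94% of KO lung cells. The 6 pools of a tissue were clustered together on 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, Python 3.11.15, scikit-learn 1.9.0). This gave 23 marrow and 24 lung clusters. Left out of these genes were Nfe2l2, Ms4a3, mitochondrial, ribosomal protein and predicted genes, and the technical, NRF2 target, interferon and MHC lists. The co-stimulation, tumour macrophage, inflammatory cytokine, haem and iron, and glutathione lists were left out too. The other lists, such as cell cycle, granule proteins, oxidative phosphorylation and glycolysis, stayed in, save members shared with a list left out. A cluster took the name of a class when at least 3 of its markers, from 279 markers of 23 classes, were 1.5-fold higher and found in 10% of its cells, with a margin of 10% over the next class. Clusters that met no class kept a number. Classes are named "-like" because no protein was measured.

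Counts were summed per pool and class. Classes with at least 20 cells in every pool were compared between KO and WT with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3 (TMM, filterByExpr), and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as threshold. Changes are fitted log2 values with their standard error, and levels are means of CPM ± SD over 3 pools. Where a group was at 0, only CPM are given, except for the interaction values of flagged genes. Tests were also run over all cells of a tissue, and the tissue-by-genotype interaction in Ly6C-high monocyte-like cells over 12 pools. Genes were named by a rule written before the data were examined: the 10 with the smallest p in each direction that passed, did not overlap between pools and reached 5 CPM, and 4 per list. Predicted genes, ribosomal proteins, mitochondrial transcripts and haemoglobins were left out of the 10. From 26 gene lists fixed beforehand, 6 of them technical, those with at least 3 genes tested were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. Class shares were tested by edgeR on cell counts with 1 common dispersion, with exact permutation tests beside it. The NRF2 score is the mean of log2(CPM + 1) over the list. Copies that share sequence, such as Gstp1, Hist1h2ap and the H2 genes, can be miscounted. Some genes that met the naming rule are not reported here.

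On simulated data with 200 changed genes, a fold of 2 was recovered for 82.1% of genes over all marrow cells, 85.1% over all lung cells, 80.6% in GMP-like, 92.5% in marrow and 85.1% in lung Ly6C-high monocyte-like, 79.1% in monocyte-derived macrophage-like and 88.1% in alveolar macrophage-like cells. A fold of 1.5 was recovered for 43.3% to 68.7%. For the interaction, 55.5% of genes with a fold of 2 were recovered. False calls at the threshold of 0.05 were 10.2% of calls over all lung cells, 9.47% in alveolar macrophage-like, 7.03% in marrow Ly6C-high monocyte-like, 6.59% over all marrow cells, 5.06% in GMP-like, 5% in lung Ly6C-high monocyte-like and 1.27% in monocyte-derived macrophage-like cells, and 1.77% for the interaction. Alternatives fixed before the data were examined were RLE normalization, the DESeq2 1.42.0 Wald test, no low-count filter, each pool left out, pool number as a block, a stricter cell filter (1000 genes, 5%), doublet calls kept and resolution 2. Chosen later were thinning every cell to 2000 UMIs, removal of genes called outside the GMP lineage, a total without NK cell-like cells, and clustering without called genes. Tests in single clusters of a class and counts of immunoglobulin RNA were also added later. Pool numbers do not pair the samples: correlations of same-numbered WT and KO pools were 0.172, -0.266 and -0.133 in marrow and -0.0164, -0.143 and -0.208 in lung.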

Results

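Myeloid cells were sorted from the bone marrow and the lungs of mice bearing KP lung tumours, at the time labelled late, with mature neutrophils excluded by the sort, and were profiled by 3' single-cell RNA-seq. Mice with floxed alleles of Nfe2l2 and no Cre (WT) were compared with mice that also carried Ms4a3Cre (KO). Nfe2l2 encodes NRF2, the transcription factor that switches on antioxidant and detoxifying genes, and Ms4a3 marks the granulocyte-monocyte progenitor (GMP) and its progeny. The comparison asks what loss of Nfe2l2 in this lineage does to myeloid cells of marrow and tumour-bearing lung. Each tissue and genotype had 3 tagged pools, 12 in all. The marrow files held 11663 WT and 9903 KO barcodes and the lung files 7664 and 10285, and 34138 of the 39515 were kept. Per pool, gene counts came to 26038789 to 41524252 UMIs in WT marrow, 27921633 to 30178042 in KO marrow, 17064374 to 27708230 in WT lung and 15996099 to 20211504 in KO lung. The median depth of kept lung cells was 6613 to 8137 UMIs in WT pools and 3190 to 4116 in KO pools. Nothing in the labels ties a pool to a separate animal, so p-values measure the spread between pools, which may be technical. The 3 pools of a group came from 1 gene expression library, so library and genotype cannot be told apart. Only KO mice carried Ms4a3Cre, so effects of the Cre or of the altered Ms4a3 locus cannot be told apart from loss of Nfe2l2.

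The targeted gene was measured first. Nfe2l2 (chromosome 2, 75675513 to 75704663, GRCm38.p6) was found in lung at 213, 199 and 199 CPM in the WT pools and 150, 135 and 125 CPM in the KO pools. Over all lung cells it fell by 0.69 ± 0.07 on the log2 scale (SE, adjusted p = 0.00023), and in alveolar macrophage-like cells from 202 ± 20.7 to 123 ± 11.7 CPM (SD, n = 3; log2 change -0.73 ± 0.09, adjusted p = 0.000384). In marrow it was at 81.5, 83.5 and 83.9 CPM in the WT pools and 115, 104 and 115 CPM in the KO pools, higher in KO (log2 change 0.32 ± 0.06, adjusted p = 0.0158). That marrow call was lost without WT pool 3 (0.32), KO pool 1 (0.30) or KO pool 3 (0.30). By class, marrow Nfe2l2 went from 89.3 ± 1.48 to 168 ± 11.7 CPM in immature neutrophil-like cells and from 62.3 ± 3.82 to 72.9 ± 6.23 CPM in GMP-like cells (0.14 ± 0.11, adjusted p = 0.51). In Ly6C-high monocyte-like cells the changes were -0.20 ± 0.07 in marrow (adjusted p = 0.0635) and -0.27 ± 0.09 in lung (adjusted p = 0.0523). The labels do not say which part of Nfe2l2 is deleted, and a 3' tag outside that part checks nothing, so these levels do not test the deletion.

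Ms4a3 (chromosome 19, 11629499 to 11640851), whose locus drives the Cre, separated the genotypes in marrow. It was at 407, 240 and 282 CPM in the WT pools and 158, 125 and 96.1 CPM in the KO pools. In GMP-like cells it fell from 1210 ± 160 to 498 ± 87.1 CPM (SD, n = 3; log2 change -1.37 ± 0.10, adjusted p = 6.69e-08), and in marrow Ly6C-high monocyte-like cells from 74.2 ± 11.9 to 29.2 ± 4.14 CPM (-1.43 ± 0.13, adjusted p = 0.000112). Over all marrow cells the log2 change was -1.40 ± 0.22 (adjusted p = 0.0149), a call lost without WT pool 3 (-1.48), KO pool 2 (-1.38) or KO pool 3 (-1.23). Lung cells held too little Ms4a3 for a test, with 103 UMIs in all WT pools and 4 in all KO pools.

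**Figure D1:**
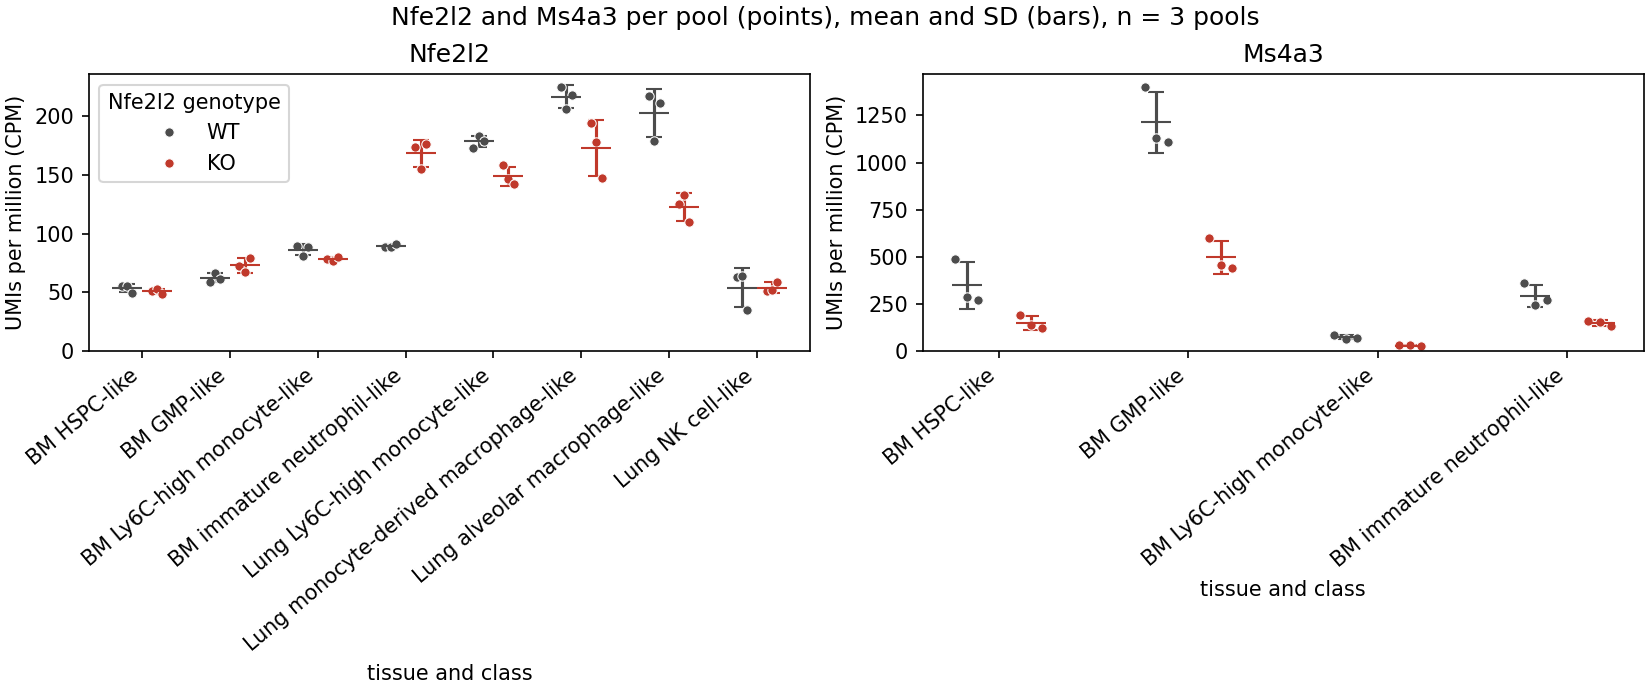
Levels of Nfe2l2 and Ms4a3 in CPM (y axis) in each WT and KO pool by cell class, with points for pools and bars for the mean and SD (n = 3). Ms4a3 in GMP-like cells was 1210 ± 160 CPM in WT and 498 ± 87.1 CPM in KO pools.

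Over all marrow cells the genes with the smallest p included Hist1h2ap, a histone H2A gene (118 ± 21.5 to 746 ± 19 CPM, log2 change 2.55 ± 0.13, adjusted p = 2.43e-05), and Gstp1, a glutathione transferase (6.36 ± 0.638 to 22.4 ± 0.234 CPM, 1.72 ± 0.08, adjusted p = 1.75e-05). Gzma, a granzyme of cytotoxic lymphocytes, also rose (1.40 ± 0.10, adjusted p = 0.000278). The largest falls among them were those of Iglc1, an immunoglobulin light chain constant gene (259 ± 93.7 to 6.03 ± 3.38 CPM, -5.54 ± 0.38, adjusted p = 0.000177), and Wdfy1, an endosomal adaptor of Toll-like receptor signalling (44.1 ± 0.967 to 16.2 ± 0.291 CPM, -1.54 ± 0.05, adjusted p = 2.15e-06). Of 32 NRF2 targets, 2 rose and 10 fell (2 and 11 adjusted over the list alone), with a median log2 change of -0.14 (camera adjusted p = 0.0072, and adjusted p = 0.727 with an estimated correlation). Of 27 oxidative phosphorylation genes, 21 fell and none rose (24 and 0 adjusted over the list alone, median -0.26, camera adjusted p = 9.08e-12, and adjusted p = 0.727 with an estimated correlation). Mitochondrially encoded transcripts went the other way, with 3 of 13 rising (camera adjusted p = 0.00401, and adjusted p = 0.727 with an estimated correlation), while 3 of 15 dissociation genes fell (median -0.25, adjusted p = 0.00491, and adjusted p = 0.727 with an estimated correlation). In all, 606 genes were higher and 1128 lower in KO of 12895 tested. The count changed strongly with pools left out: it was 56 without WT pool 3, 66, 86 and 85 without KO pool 1, 2 or 3, and 2942 without WT pool 2. Genes with an unadjusted edgeR p below 0.05 changed less. They numbered 4159 with all pools, 3267 without WT pool 3, and 3327, 3384 and 3255 without KO pool 1, 2 or 3.

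Over all lung cells, which also takes in the shift of cell types described next, plasma cell transcripts set the genotypes apart. Igkc, the kappa light chain, was at 0.634 ± 0.342 CPM in WT and 2550 ± 585 CPM in KO pools, and Igha, the IgA heavy chain, at 0.273 ± 0.141 and 2170 ± 486 CPM (SD, n = 3). Spn, a sialoglycoprotein of Ly6C-low monocytes and lymphocytes, rose (1.62 ± 0.10, adjusted p = 5.06e-05), as did Cd2, an adhesion molecule of T and NK cells (1.26 ± 0.05, adjusted p = 4.04e-06). Macrophage genes fell, among them Gpnmb (1070 ± 16.9 to 386 ± 71.6 CPM, -1.58 ± 0.12, adjusted p = 7.85e-05), Trem2, a lipid-sensing receptor (-1.23 ± 0.12, adjusted p = 0.000215), and the scavenger receptor Msr1 (-0.89 ± 0.05, adjusted p = 4.52e-05). Of 25 tumour macrophage genes, 18 fell and 1 rose (20 and 2 adjusted over the list alone, median -0.59, camera adjusted p = 5.75e-08, and adjusted p = 0.293 with an estimated correlation). Of 33 NRF2 targets, 19 fell and 1 rose (21 and 1 adjusted over the list alone, median -0.37, adjusted p = 1.15e-05, and adjusted p = 0.297 with an estimated correlation). The iron-storage genes Fth1 (-0.86 ± 0.10, adjusted p = 0.000475) and Ftl1 (-0.75 ± 0.10, adjusted p = 0.000695) and the thioredoxin reductase Txnrd1 (-0.55 ± 0.07, adjusted p = 0.00063) were among them. Of 20 genes of glycolysis and hypoxia, 16 fell (17 adjusted over the list alone, median -0.51, adjusted p = 5.7e-08, and adjusted p = 0.297 with an estimated correlation). Of 30 type I interferon response genes, 12 rose and 1 fell (median 0.24, adjusted p = 0.00132, and adjusted p = 0.649 with an estimated correlation). All 7 neutrophil RNA markers fell (median -2.10, adjusted p = 0.00416, and adjusted p = 0.46 with an estimated correlation), as did 7 of 15 dissociation genes (median -0.33, adjusted p = 4.5e-05, and adjusted p = 0.293 with an estimated correlation). In all, 1954 genes were higher and 2029 lower of 12787 tested.

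The make-up of the sorted and kept lung cells differed between genotypes. Monocyte-derived macrophage-like cells, a cluster with complement C1q genes among its markers, made up 22% ± 3.23 of kept lung cells in WT and 5.90% ± 0.792 in KO pools (SD, n = 3; log2 change -1.90 ± 0.27, adjusted p = 4.08e-06). Their share of myeloid cells was 30.2% in WT and 9.57% in KO. A cluster led by Ccl24, Ccl12, Ccl2 and Arg1 fell from 10.8% ± 1.51 to 3.14% ± 1.19 (-1.78 ± 0.30, adjusted p = 3.42e-05), and a small cluster led by Prg4, Alox15 and Saa3 from 2.19% ± 1.5 to 0.329% ± 0.257 (-2.66 ± 0.49, adjusted p = 9.8e-05). Ly6C-low monocyte-like cells, the patrolling monocytes, rose from 1.81% ± 1.16 to 6.37% ± 1.90 (1.86 ± 0.41, adjusted p = 0.000613), and NK cell-like cells from 13.3% ± 1.54 to 29.2% ± 5.50 (1.14 ± 0.26, adjusted p = 0.000914). Plasma cell-like cells were 1 cell of the WT pools and 75 of the KO pools (5.29 ± 0.71, adjusted p = 3.49e-06). NK cell-like and plasma cell-like cells are not myeloid, so the purity of the myeloid sort can set their shares. A larger share of NK cell-like cells also lowers the shares of all other classes. Ly6C-high monocyte-like cells were 12.7% ± 3.16 in WT and 15.5% ± 1.95 in KO (0.29 ± 0.27, adjusted p = 0.369).

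The calls for 2 further lung classes were fragile. Alveolar macrophage-like cells were 10.1% ± 2.60 in WT and 16.6% ± 1.59 in KO (log2 change 0.71 ± 0.27, adjusted p = 0.0362), a call lost without WT pool 2 (0.56) or 3 (0.66), without KO pool 1 (0.63), 2 (0.73) or 3 (0.76), with a stricter cell filter (0.62), and with clustering without called genes (0.52). Neutrophil-like cells were 11% ± 1.46 in WT and 5.87% ± 0.394 in KO (-0.91 ± 0.26, adjusted p = 0.00557), a call lost without KO pool 2 (-0.86) and with NK cell-like cells left out of the total (-0.62). Mature neutrophils were excluded by the sort, and high mitochondrial content removed 25.1% of WT and 15.9% of KO lung barcodes, so both steps can set these shares. Lung KO cells were also shallower. With edgeR, 8 of 19 lung classes passed the test, and exact two-sided permutation tests of these 8 shares each gave the smallest p that 3 against 3 pools allow, 0.1. In marrow 0 of 16 classes passed with edgeR, and 3 had an unadjusted p below 0.05. They were neutrophil-like cells (8.74% ± 0.385 to 11.5% ± 0.409, adjusted p = 0.0711), a cluster numbered 10 (4.02% ± 0.514 to 2.62% ± 0.388, adjusted p = 0.0711) and HSPC-like cells, the stem and early progenitor cells (2.41% ± 0.263 to 3.40% ± 0.673, adjusted p = 0.177). GMP-like cells were 5.94% ± 1.55 in WT and 3.97% ± 1.16 in KO (-0.58 ± 0.29, adjusted p = 0.277), and marrow Ly6C-high monocyte-like cells 26.4% ± 3.01 and 21.8% ± 3.44 (adjusted p = 0.285).

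**Figure D2:**
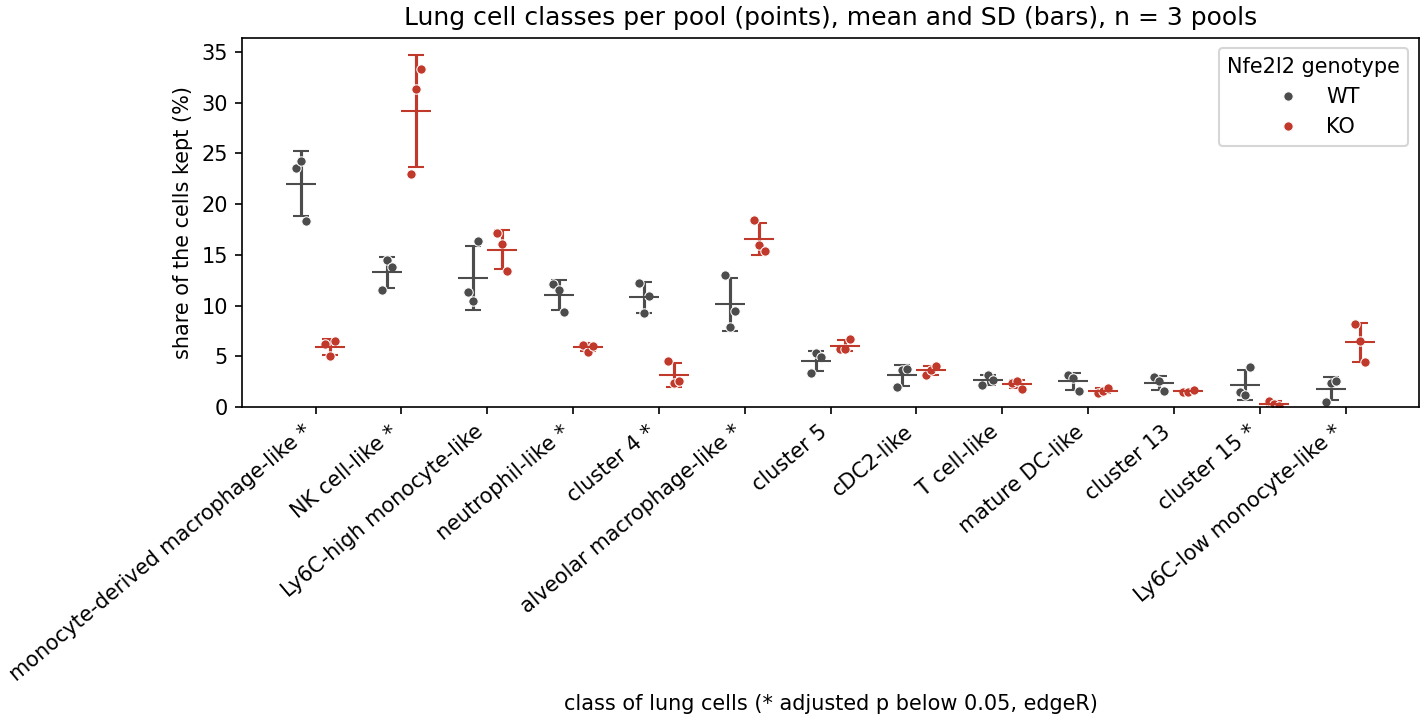
Share of kept lung cells (y axis, %) of 13 classes in each WT and KO pool, with points for pools, bars for the mean and SD (n = 3), and an asterisk for classes that passed the test. Monocyte-derived macrophage-like cells were 22% in WT and 5.90% in KO pools, and NK cell-like cells 13.3% and 29.2%.

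In GMP-like cells, where Ms4a3 is expressed, transcripts of neutrophil granules and alarmins fell in KO. S100a9, an alarmin subunit abundant in neutrophils, went from 14000 ± 1620 to 8210 ± 817 CPM (SD, n = 3; log2 change -0.86 ± 0.07, adjusted p = 9.72e-08), and its partner S100a8 from 15300 ± 1800 to 10200 ± 898 CPM (-0.68 ± 0.07, adjusted p = 2.85e-06). Camp, the cathelicidin of secondary granules, fell by 0.91 ± 0.09 (4150 ± 527 to 2360 ± 376 CPM, adjusted p = 2.4e-06). Ctsg, a serine protease of primary granules (3060 ± 114 to 2220 ± 178 CPM, -0.55 ± 0.06, adjusted p = 1.04e-05), and Hp, haptoglobin (381 ± 33.9 to 270 ± 11.8 CPM, -0.59 ± 0.08, adjusted p = 0.000239), fell too. Of 12 granule protein genes, 7 fell and none rose (median -0.40, camera adjusted p = 7.92e-06, and adjusted p = 0.196 with an estimated correlation), and 5 of 7 neutrophil RNA markers fell (median -0.72, adjusted p = 8.93e-09, and adjusted p = 0.126 with an estimated correlation). S100a9, S100a8 and Camp are among these 5, so RNA of neutrophils was not separated from expression in GMP-like cells. Mpo, Elane, Prtn3 and Ctsg of the granule list are also markers that name the GMP class, and they were not left out of clustering. The fall of the granule list was thus not separated from how the class was formed and named. The class joined clusters 14 and 15, and cluster 14 held 44.7% to 50.5% of it in WT and 55.9% to 63.9% in KO pools. Among the genes that rose from low levels were Ms4a2, the beta chain of the high-affinity IgE receptor (2.32 ± 1.32 to 17.1 ± 1.92 CPM, 3.00 ± 0.29, adjusted p = 1.86e-06), and Ccr1, a chemokine receptor (2.18 ± 0.779 to 21.4 ± 13 CPM, 2.95 ± 0.46, adjusted p = 0.00108). The basophil protease gene Mcpt8 fell (-1.53 ± 0.36, adjusted p = 0.0233), while Ms4a2 rose, so these 2 basophil genes went opposite ways. Ms4a2 was not in the set of genes weighed later for DNA near the edited genes, so that source was not tested for it. Mid1 was at 0 CPM in every WT pool and at 22.8 ± 7.6 CPM in KO.

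Among metabolic lists in GMP-like cells, 4 of 27 oxidative phosphorylation genes fell (1 rose and 13 fell adjusted over the list alone, median -0.16, camera adjusted p = 3.51e-08, and adjusted p = 0.27 with an estimated correlation). Of 17 cholesterol synthesis genes, 3 fell (6 adjusted over the list alone, median -0.31, adjusted p = 0.000155, and adjusted p = 0.196 with an estimated correlation), with Fdps, farnesyl diphosphate synthase, at -0.53 ± 0.09 (adjusted p = 0.00342). Of 15 glutathione genes none passed over all genes and 3 fell adjusted over the list alone (median -0.21, adjusted p = 0.00089, and adjusted p = 0.196 with an estimated correlation). The NRF2 list did not pass (1 rose and 2 fell of 26, 3 and 4 adjusted over the list alone, camera adjusted p = 0.243), and its median of -0.09 and mean of 0.06 differed in sign. Its member Txn1, thioredoxin, fell from 987 ± 39.6 to 820 ± 26.5 CPM (-0.35 ± 0.06, adjusted p = 0.00342). Mitochondrial transcripts rose as a list (4 of 13, adjusted p = 1.33e-08, and adjusted p = 0.206 with an estimated correlation), led by mt-Nd3 (1.08 ± 0.07, adjusted p = 6.29e-09). Several of the strongest changes, among them Hist1h2ap (2.59 ± 0.13, adjusted p = 1.09e-10), Gstp1 (2.12 ± 0.18, adjusted p = 3.1e-07), Wdfy1 (-1.84 ± 0.14, adjusted p = 6.69e-08) and Ctsg, were also called in HSPC-like or plasmacytoid dendritic (pDC)-like cells of marrow. In all, 99 genes were higher and 191 lower of 9605 tested. The total of 290 was 164, 116 and 78 without KO pool 1, 2 or 3, 460 without WT pool 2, and 39 with each cell thinned to 2000 UMIs.

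Marrow Ly6C-high monocyte-like cells of KO pools had lower antioxidant and respiratory transcripts and higher MHC class II transcripts. Of 30 NRF2 targets, 12 fell and 1 rose (12 and 2 adjusted over the list alone, median -0.21, camera adjusted p = 0.00137, and adjusted p = 0.308 with an estimated correlation). Gclm, a subunit of the enzyme that starts glutathione synthesis, went from 74.8 ± 11.1 to 51.7 ± 2.87 CPM (SD, n = 3; log2 change -0.61 ± 0.10, adjusted p = 0.00614). Idh1, a source of NADPH, fell by 0.42 ± 0.06 (adjusted p = 0.00304), and Txn1 and the ferritin gene Fth1 fell by 0.31 ± 0.04 and 0.27 ± 0.04 (adjusted p = 0.00221 and 0.00305). The member that rose was Gstp1 (1.74 ± 0.12, adjusted p = 6.84e-06), which was also called outside the lineage and lies within 20 Mb of Nfe2l2 or Ms4a3. Of 17 glutathione genes, 6 fell (9 adjusted over the list alone, median -0.31, adjusted p = 8.14e-05, and adjusted p = 0.2 with an estimated correlation). The peroxidases Gpx3 (27.2 ± 4.81 to 13 ± 2.24 CPM, -1.15 ± 0.16, adjusted p = 0.00208) and Gpx4 (-0.31 ± 0.05, adjusted p = 0.00262) were among them. Of 27 oxidative phosphorylation genes, 18 fell (21 adjusted over the list alone, median -0.20, adjusted p = 1.45e-11, and adjusted p = 0.347 with an estimated correlation). Of 9 MHC class II genes, 3 rose (5 rose and 1 fell adjusted over the list alone, median 0.95, adjusted p = 0.00225, and adjusted p = 0.308 with an estimated correlation), from low levels. Cd74, the invariant chain, rose from 26.3 ± 4.69 to 53.7 ± 3.92 CPM (0.98 ± 0.12, adjusted p = 0.000824). H2-Aa rose from 2.48 ± 0.518 to 6.81 ± 1.58 CPM (1.39 ± 0.25, adjusted p = 0.00727), a call lost without KO pool 3 (1.21) and at clustering resolution 2 (0.21).

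Other genes of marrow Ly6C-high monocyte-like cells pointed in both directions. Thbs1, the matrix protein thrombospondin, fell from 103 ± 18.4 to 38.9 ± 20.1 CPM (log2 change -1.46 ± 0.24, adjusted p = 0.00575). Ankrd37, a hypoxia-responsive gene, fell from 14.5 ± 1.54 to 2.26 ± 0.321 CPM (-2.74 ± 0.18, adjusted p = 5.21e-06), and Grk5, a receptor kinase, by 0.87 ± 0.10 (adjusted p = 0.000568). Nfkb1, a subunit of NF-kappaB, rose by 0.33 ± 0.06 (adjusted p = 0.00698). Mitochondrial transcripts rose (10 of 13, median 0.15, camera adjusted p = 1.86e-09, and adjusted p = 0.308 with an estimated correlation). The dissociation list fell (4 of 15, median -0.22, adjusted p = 0.00137, and adjusted p = 0.398 with an estimated correlation), as did the neutrophil RNA list (4 of 7, median -0.34, adjusted p = 0.0162, and adjusted p = 0.502 with an estimated correlation). In all, 473 genes were higher and 762 lower of 10427 tested. The total of 1235 was 762, 2002 and 459 without WT pool 1, 2 or 3, 294, 492 and 205 without KO pool 1, 2 or 3, and 444 with thinned cells.

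In lung Ly6C-high monocyte-like cells, interferon response and antigen presentation genes were higher in KO pools. Rsad2 (viperin) rose from 15.6 ± 6.38 to 62.6 ± 10.7 CPM (SD, n = 3; log2 change 1.98 ± 0.21, adjusted p = 6.85e-06). The interferon-induced genes Ifit2 (8.68 ± 1.5 to 37.0 ± 9.44 CPM, 2.11 ± 0.24, adjusted p = 1.06e-05), Ifit3 (2.03 ± 0.27, adjusted p = 7.95e-05) and Ifit1 (1.33 ± 0.19, adjusted p = 0.000112) rose with it. Of 29 type I interferon response genes, 21 rose and none fell (24 and 0 adjusted over the list alone, median 0.66, camera adjusted p = 7.49e-20, and adjusted p = 0.241 with an estimated correlation). Of 14 MHC class I genes, 8 rose (12 adjusted over the list alone, median 0.37, adjusted p = 6.28e-07, and adjusted p = 0.241 with an estimated correlation). These included B2m, the light chain of class I (2210 ± 211 to 2850 ± 323 CPM, 0.35 ± 0.08, adjusted p = 0.00682), and Tapbp, tapasin of the peptide-loading complex (330 ± 44.7 to 447 ± 23.5 CPM, 0.43 ± 0.09, adjusted p = 0.00443). Of 8 MHC class II genes, 5 rose (median 0.57, adjusted p = 3.82e-05, and adjusted p = 0.241 with an estimated correlation), with H2-DMb1 at 0.57 ± 0.11 (adjusted p = 0.00288). H2-Eb1 rose by 0.68 ± 0.14 (adjusted p = 0.00435) with edgeR but did not pass with DESeq2 (0.66, adjusted p = 0.132). The mean log2(CPM + 1) of the class II list changed by 0.445 here (exact permutation p = 0.2). In lung NK cell-like cells it changed by 0.461 (3.29 ± 0.433 to 3.75 ± 0.0596, exact permutation p = 0.2), and in alveolar macrophage-like cells by -0.375. RNA of other cells was thus not separated from a monocyte response for this list. Ccl5, a chemokine for T cells (9.90 ± 3.07 to 35.2 ± 12.6 CPM, 1.81 ± 0.27, adjusted p = 0.000244), and Slamf7, an activating receptor (1.90 ± 0.32, adjusted p = 0.000729), were among the 3 co-stimulation genes of 9 that rose, and 1 fell (camera adjusted p = 0.162). The class joined clusters 3 and 8, and cluster 8 held 14.7% to 30.05% of it in WT and 28.4% to 42.4% in KO pools.

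Genes of glycolysis, glutathione metabolism and the unfolded protein response went down in the same lung cells. Among NRF2 targets, Txnrd1 fell from 59.8 ± 5.76 to 35.5 ± 6.34 CPM (log2 change -0.78 ± 0.15, adjusted p = 0.00169). Pgd, an enzyme of the pentose phosphate pathway, fell from 337 ± 33.2 to 252 ± 7.44 CPM (-0.44 ± 0.09, adjusted p = 0.00275). They were 2 of the 5 NRF2 targets of 27 that fell (1 rose and 5 fell adjusted over the list alone). The list itself did not pass (median -0.04, camera adjusted p = 0.207). Gpx3 (-1.49 ± 0.22, adjusted p = 0.0002) and Gpx4 (-0.43 ± 0.08, adjusted p = 0.00207) fell within the glutathione list (4 of 15, adjusted p = 0.00537, and adjusted p = 0.345 with an estimated correlation). Of 18 genes of glycolysis and hypoxia, 5 fell and 1 rose (9 and 1 adjusted over the list alone, median -0.30, adjusted p = 0.000111, and adjusted p = 0.254 with an estimated correlation), with Eno1, enolase, at -0.72 ± 0.09 (adjusted p = 2.07e-05). Eno1 fell in lung NK cell-like cells too (-0.66, edgeR adjusted p = 0.000821). Of 10 unfolded protein response genes, 4 fell and 1 rose (median -0.33, adjusted p = 0.00712, and adjusted p = 0.241 with an estimated correlation). The chaperone Hspa5 (640 ± 111 to 344 ± 26.7 CPM, -0.91 ± 0.10, adjusted p = 1.1e-05) and the transcription factor Xbp1 (-0.83 ± 0.08, adjusted p = 1.86e-06) fell. Of 21 tumour macrophage genes, 6 fell and 3 rose: the fatty acid binder Fabp5 (-0.94 ± 0.10, adjusted p = 9.26e-06) and the protease Ctsd fell, while Lpl, lipoprotein lipase (1.21 ± 0.22, adjusted p = 0.00112), and the lipid receptor Cd36 (1.42 ± 0.28, adjusted p = 0.0024) rose. The call of the tumour macrophage list (median -0.28, mean -0.08, camera adjusted p = 0.0466, and adjusted p = 0.241 with an estimated correlation) was lost without WT pool 2 (adjusted p = 0.0746) or KO pool 1 (adjusted p = 0.111). Bhlhe40, a transcription factor, fell from 85.0 ± 9.21 to 30.1 ± 6.28 CPM (-1.52 ± 0.15, adjusted p = 2.29e-06). Cd38, an NAD hydrolase, fell from 38.4 ± 14.1 to 1.82 ± 1.37 CPM (-4.40 ± 0.38, adjusted p = 6.32e-07). Hpgd, which breaks down prostaglandins, rose from 31.2 ± 9.11 to 115 ± 7.09 CPM (1.90 ± 0.15, adjusted p = 3.4e-07). Hpgd in lung and Cd36 in marrow were among the 10 leading genes of Ly6C-low monocyte-like clusters, and Hpgd also of cluster 8 of this class, so these rises can reflect a shift between monocyte states.

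RNA of other sources moved in lung Ly6C-high monocyte-like cells as well. All 3 neutrophil RNA markers tested fell (median -5.19, camera adjusted p = 0.00222, and adjusted p = 0.254 with an estimated correlation), with S100a8 at 865 ± 639 CPM in WT and 23.3 ± 3.82 CPM in KO. Of 15 dissociation genes, 6 fell (median -0.21, adjusted p = 0.000884, and adjusted p = 0.241 with an estimated correlation). Igkc was at 0 CPM in every WT pool and at 58.5 ± 6.51 CPM in KO. The classical monocyte marker Vcan, used to name the class, and Chil3 were lower in KO and are not read as results. In all, 450 genes were higher and 400 lower of 8873 tested. The total of 850 was 434 without WT pool 1, 541 without KO pool 1, 474 with DESeq2 and 358 with thinned cells.

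**Figure D3:**
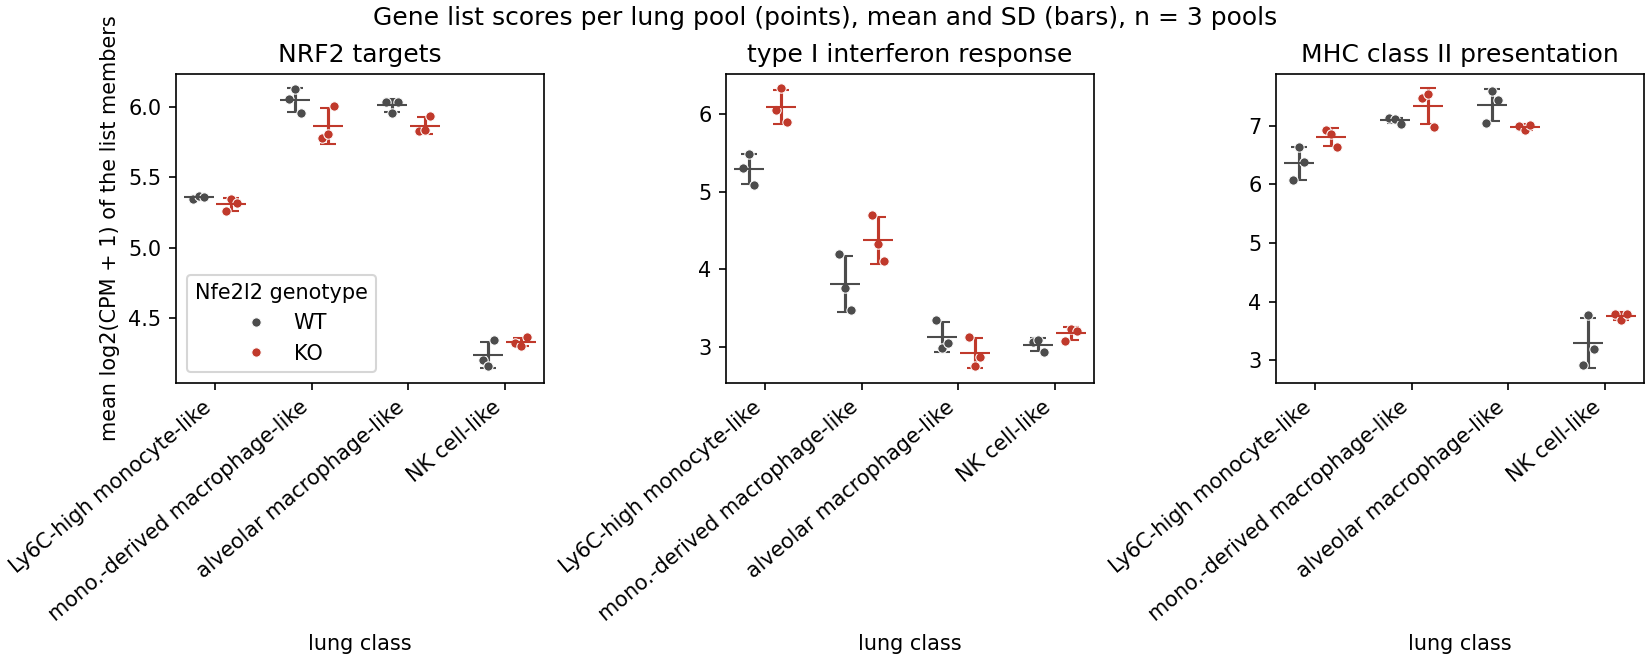
Mean log2(CPM + 1) of the NRF2 target, type I interferon response and MHC class II lists (y axis) in each WT and KO lung pool for 4 classes, with points for pools and bars for the mean and SD (n = 3). The NRF2 score of Ly6C-high monocyte-like cells was 5.36 in WT and 5.31 in KO pools.

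Far fewer genes passed in monocyte-derived macrophage-like cells of the lung, of which 1269 WT and 502 KO cells were kept. Gdf3, a member of the TGF-beta family, rose from 4.91 ± 1.15 to 15.3 ± 2.59 CPM (SD, n = 3; log2 change 1.68 ± 0.23, adjusted p = 0.00405). Apoc2, the activator of lipoprotein lipase, rose from 94.8 ± 6.09 to 156 ± 15.1 CPM (0.70 ± 0.09, adjusted p = 0.00266), and Lrmda from 1.67 ± 0.157 to 13.9 ± 5.02 CPM (3.02 ± 0.30, adjusted p = 0.000215). Wdfy1 fell (51.0 ± 1.1 to 17.3 ± 3.15 CPM, -1.54 ± 0.12, adjusted p = 2.16e-05). With thinned cells the Apoc2 change was 0.29 and no longer passed. Of 31 NRF2 targets none passed over all genes and 9 fell adjusted over the list alone (median -0.18, camera adjusted p = 4.31e-09, and adjusted p = 0.457 with an estimated correlation). The members with the smallest p were Mgst1, a glutathione transferase (305 ± 22.3 and 243 ± 6.62 CPM, -0.34 ± 0.08, adjusted p = 0.0733), and Txnrd1 (113 ± 6.13 and 87.8 ± 10.8 CPM, -0.37 ± 0.09, adjusted p = 0.108). The type I interferon list was higher (0 of 30 passed over all genes, 6 rose adjusted over the list alone, median 0.33, adjusted p = 1.43e-08, and adjusted p = 0.541 with an estimated correlation). Mitochondrial transcripts also rose as a list (1 of 13, adjusted p = 9.24e-05, and adjusted p = 0.541 with an estimated correlation).

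MHC class II genes were higher in the same macrophages, with 3 of 9 rising (5 adjusted over the list alone, median 0.46, camera adjusted p = 2.4e-07, and adjusted p = 0.457 with an estimated correlation). The mean log2(CPM + 1) of the list changed by 0.244 here and by 0.461 in lung NK cell-like cells (exact permutation p = 0.4 and 0.2). Technical lists were called too. The mitochondrial list was higher (median 0.10, camera adjusted p = 9.24e-05, and adjusted p = 0.541 with an estimated correlation). The neutrophil RNA list was called lower (adjusted p = 0.0328, and adjusted p = 0.541 with an estimated correlation), although none of its 5 genes passed and their median was 0.02. That call was lost without WT pool 1, 2 or 3 (adjusted p = 0.742, 0.162 and 0.0941) and turned to higher without KO pool 3 (adjusted p = 0.7). H2-Aa was at 1190 ± 79.7 CPM in WT and 1840 ± 366 CPM in KO (log2 change 0.61 ± 0.11, adjusted p = 0.0297). Its call was lost without WT pool 1 (0.61), 2 (0.65) or 3 (0.56), without KO pool 1 (0.55) or 2 (0.50), and at clustering resolution 2 (0.28). Mmp12, macrophage elastase, went from 1580 ± 219 to 1100 ± 73.4 CPM (-0.54 ± 0.10, adjusted p = 0.023), a call lost without WT pool 2 (-0.55) or 3 (-0.43) and without KO pool 1 (-0.54) or 2 (-0.50). C1qa and C1qc, which name the class, are not read as results, and Igkc was at 0.425 ± 0.357 CPM in WT and 43.5 ± 1.58 CPM in KO. In all, 39 genes were higher and 20 lower. The total of 59 was 34 without WT pool 1, 35 without WT pool 3, 30, 26 and 141 without KO pool 1, 2 or 3, 92 with DESeq2 and 22 at resolution 2.

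Alveolar macrophage-like cells, mostly of embryonic and not of GMP origin in the healthy lung, were set beside the GMP-derived classes. They are not shown to be an unaffected control, since Nfe2l2 fell in them (202 ± 20.7 to 123 ± 11.7 CPM, -0.73 ± 0.09, adjusted p = 0.000384). Ms4a3 was at 16.1 CPM in WT pool 1 but at 2.63 and 1.76 CPM in WT pools 2 and 3. Among the genes that fell was Itgam, the integrin CD11b (50 ± 2.11 to 12.5 ± 0.733 CPM, SD, n = 3; log2 change -2.00 ± 0.12, adjusted p = 3.75e-07). Another was Apoe, apolipoprotein E (591 ± 158 to 86.1 ± 22.4 CPM, -2.79 ± 0.19, adjusted p = 1.8e-06). Apoe fell in lung NK cell-like cells too (-0.879, edgeR adjusted p = 0.000265), so RNA of other cells was not separated from a change in this class. Apoe is a marker used to name the monocyte-derived macrophages, and Plac8, which fell too (-1.90 ± 0.11, adjusted p = 2.94e-07), names Ly6C-high monocytes. Of 24 tumour macrophage genes, 10 fell and 2 rose (13 and 5 adjusted over the list alone, median -0.26, camera adjusted p = 0.00267, and adjusted p = 0.382 with an estimated correlation). Gpnmb fell from 308 ± 74.6 to 146 ± 19.1 CPM (-1.07 ± 0.14, adjusted p = 0.000554). The tetraspanin Cd9 was among those that rose (0.37 ± 0.05, adjusted p = 0.000434). Of 30 NRF2 targets, 6 fell and 1 rose (8 and 1 adjusted over the list alone, median -0.12, adjusted p = 0.00194, and adjusted p = 0.382 with an estimated correlation). Slc7a11, the cystine importer that feeds glutathione synthesis, fell from 61.7 ± 4.57 to 26.7 ± 6.48 CPM (-1.20 ± 0.15, adjusted p = 0.00037), and Gpx3 from 14.5 ± 2.58 to 3.84 ± 1.88 CPM (-1.91 ± 0.30, adjusted p = 0.0017).

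Presentation and cell cycle genes were also lower in alveolar macrophage-like cells. Of 11 MHC class II genes, 5 fell (median -0.51, camera adjusted p = 0.00317, and adjusted p = 0.458 with an estimated correlation), with H2-Eb1 going from 444 ± 109 to 269 ± 1.68 CPM (log2 change -0.71 ± 0.13, adjusted p = 0.00518). Of 17 interferon gamma response genes, 6 fell (11 adjusted over the list alone, median -0.60, adjusted p = 4.64e-07, and adjusted p = 0.382 with an estimated correlation), among them Ifi47, an immunity-related GTPase (-0.89 ± 0.17, adjusted p = 0.00567). Irf8, a transcription factor of the monocyte lineage, fell by 0.64 ± 0.12 (adjusted p = 0.00518). Of 26 cell cycle genes, 8 fell (16 adjusted over the list alone, median -0.44, adjusted p = 3.86e-10, and adjusted p = 0.382 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell by 0.61 ± 0.12 (adjusted p = 0.0081), a call lost without WT pool 1 (-0.53) and with a stricter cell filter (-0.58). The cycling cluster 11 held 20.9% to 23.7% of this class in WT and 13.5% to 15.2% in KO pools. Neutrophil RNA markers fell (5 of 6, median -4.38, adjusted p = 0.00308, and adjusted p = 0.425 with an estimated correlation), with S100a9 at 727 ± 617 CPM in WT and 39.8 ± 6.74 CPM in KO. Mitochondrial transcripts rose (5 of 13, median 0.14, adjusted p = 3.47e-07, and adjusted p = 0.382 with an estimated correlation). In all, 327 genes were higher and 405 lower. The total of 732 was 434 without WT pool 1, 403 and 401 without KO pool 1 or 2, 383 with a stricter cell filter and 197 with thinned cells.

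The NRF2 list was compared between lung classes as a score. The score of Ly6C-high monocyte-like cells minus that of alveolar macrophage-like cells of the same pool was -0.65 ± 0.05 in WT and -0.56 ± 0.07 in KO (SD, n = 3), a difference of 0.10 (exact two-sided permutation p = 0.2). For monocyte-derived macrophage-like cells it was 0.03 ± 0.13 and 0.00 ± 0.06, a difference of -0.04 (exact permutation p = 0.7). Single pools moved both differences. The first was 0.0613 without KO pool 2 and 0.128 without KO pool 3, and the second 0.0286 without WT pool 2 and -0.0999 without WT pool 3. The KO response of the list was thus not shown to differ between these GMP-derived classes and alveolar macrophages. Nfe2l2 fell in the latter too, which limits this comparison, and 3 against 3 pools cannot give a p below 0.1.

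Ly6C-high monocyte-like cells were found in both tissues and allowed a test of whether the KO effect differed between them. Of 8782 genes tested in both, 440 were higher in marrow KO and 436 in lung KO, with 109 shared against 21.8 for independent lists (Fisher's exact p = 5.84e-49). The lower genes numbered 739 and 388, with 158 shared against 32.6 (Fisher's exact p = 2.43e-72), and genes are not independent replicates. The marrow and lung comparisons had separate control libraries. The interaction term called 70 genes over the 12 pools, 24 with a higher and 46 with a lower effect in lung. Lmo4, a LIM-domain transcription regulator, had a log2 change of 0.65 in lung and -0.03 in marrow (difference 0.66), and Isg20, an interferon-induced exonuclease, 1.43 and -0.34 (difference 1.76). Eno1 fell in lung (-0.72) and rose in marrow (0.58), a difference of -1.33. It also rose in marrow HSPC-like cells (0.65) and fell in lung NK cell-like cells (-0.66), so this difference was not particular to monocyte-like cells. The total of 70 was 161 without WT pool 1 of marrow, 41 without KO pool 1 of lung and 119 with DESeq2.

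In the other classes with at least 20 cells in every pool, 715 genes were higher and 1160 lower in KO, summed over 19 classes. Immature neutrophil-like cells of marrow had 222 higher and 456 lower, HSPC-like cells 28 and 106, NK cell-like cells of lung 27 and 54, and the lung cluster led by Ccl24 and Arg1 38 and 14. Leaving out 1 pool moved these totals. The 678 of immature neutrophil-like cells were 218, 191 and 105 without KO pool 1, 2 or 3, 303 without WT pool 3 and 1002 without WT pool 2. The 134 of HSPC-like cells were 41 and 59 without KO pool 1 or 3 and 72 without WT pool 2, and the 81 of NK cell-like cells 47 without WT pool 1. HSPC-like cells had 43 at clustering resolution 2 and 214 without a low-count filter. NK cell-like cells of lung had 32 with DESeq2 and 130 with pool number as a block. The 52 of the Ccl24 and Arg1 cluster were 18 and 88 without KO pool 1 or 3, and 33 and 34 without WT pool 1 or 3. The summed total of 1875 was 821 without KO pool 1, 1078 without KO pool 2 and 1092 without KO pool 3.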

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

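Of the tests in this part, those chosen only after the result was seen include thinning, the sign in lung NK cell-like cells and the ratio outside to inside the GMP lineage. They also include the interferon list in NK cell-like cells and in single clusters, the immunoglobulin tests and the composition of each split of the interaction. A test of the difference between tissues flagged 70 genes in Ly6C-high monocyte-like cells, and the values below are lung minus marrow KO effects on the log2 scale. Higher in lung were Igha (8.08), Igkc (10.8) and Jchain (8.74), which had a group at or near 0, so that these folds are no measure of size. Lmo4 (0.66), Pttg1 (0.811), Gngt2 (1.08), Abi3 (1.08), Smpdl3b (1.79), Klra2 (0.66), Tmsb4x (0.265), Isg20 (1.76) and Mmp14 (5.83) were higher too. Without KO pool 1 of lung, Abi3 (0.959) and Klra2 (0.63) did not pass. Lower in lung were Eno1 (-1.33), Gstp1 (-1.94), Tfec (-1.82), Hist1h2ap (-2.99), Erh (-1.68), Rnf149 (-0.982), Coro2a (-0.997), Prtn3 (-1.52), Cd24a (-1.68), Fabp5 (-0.907), S100a8 (-4.24), S100a9 (-5.14), mt-Nd3 (-0.47), mt-Nd4l (-0.625) and mt-Atp8 (-0.812). S100a8 and S100a9 are neutrophil RNA markers. Eno1, Gstp1, Hist1h2ap, Erh, Prtn3, mt-Nd3 and mt-Nd4l were called alike in marrow HSPC-like or pDC-like cells, so their marrow changes were not particular to monocyte-like cells. Of 100 splits of the pools within tissues, 2 gave at least 70 genes, the real one included. That share is under 0.05, which argues against chance in both tissues at once. The other one gave 469, several times the real count, which points to a structure of the samples. It kept the lung genotypes and set marrow pools WT 1, WT 3 and KO 3 against the rest. The 10 splits that kept the lung genotypes, the real one among them, gave 16 to 469 genes, the 9 others that kept the marrow genotypes gave 4 to 13, and splits that kept the genotypes of neither tissue at most 1. The counts were thus higher where the lung genotypes were kept, but they also changed with the marrow grouping. Splits that mixed the genotypes of both tissues gave almost no genes, so most of the 100 could not compete. Among the 10 that kept the lung genotypes the real one was not the highest, so chance in the marrow grouping is left open. The 70 genes do not by themselves show how far the tissues differ.

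The first pattern weighed was a set of 133 genes (26 higher, 107 lower) called alike in marrow cells of the GMP lineage and in HSPC-like or pDC-like cells, classes named as outside that lineage. Wdfy1 is one of them, at -1.84 in GMP-like, -1.71 in HSPC-like and -0.80 in lung NK cell-like cells. Many of the lower genes are ribosomal protein genes with small changes, such as Rpl27 (-0.259 in GMP-like and -0.346 in HSPC-like cells). Oxidative phosphorylation genes such as Cox8a (-0.245 and -0.312) and Atp5g1 (-0.383 and -0.602) belong to the set as well, so their falls were not confined to the GMP lineage. In the NK cell-like cells 9 genes of the set were called the same way and 2 the opposite way: Gm10076 (1.79 in GMP-like and -0.53 in NK cell-like cells) and Eno1 (0.56 and -0.66). A difference of the marrow library pair only is left open. Of the genes tested in lung NK cell-like cells, 64.7% (75 of 116) had the same sign there, but among the higher genes it was 10 of 19 (95% interval 28.9% to 75.6%), against 50.2% of other genes. Among the lower genes it was 65 of 97 (56.7% to 76.2%, against 49.8%), and genes that move together are not independent. The median ratio of the change in NK cell-like cells to that inside the lineage was 0.193 (quartiles -0.22 to 0.585). In lung alveolar macrophage-like cells, 82 of 128 genes tested had the same sign, and 19 were called the same way. Gm47283 (4.49) and mt-Nd3 (0.701) rose there as in marrow. The marrow rises of Hist1h2ap (-0.885), Hist1h2ae (-0.924), Kpna2 (-0.77) and Erh (-0.401) were called lower there, so these rises were not shared by lung. Inherited DNA near the edited genes is argued against as the cause of the set as a whole. Of 123 genes with coordinates, 4 (3.25%, 95% interval 0.893% to 8.12%) lay within 20 Mb of Nfe2l2 or Ms4a3, against 3.49% of all tested genes (Fisher's exact p = 1). The interval does not exclude a modest excess. For these 4, Asrgl1, Cox8a, Gstp1 and Ms4a3, inherited DNA is left open, and inherited DNA elsewhere in the genome was not tested. The median ratio of the change outside to inside the lineage was 1.28, but the genes were chosen for being called on both sides, so loss of NRF2 in the lineage cannot be told apart from the rest.

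The second pattern was immunoglobulin RNA in every lung class of the KO pools. Free RNA of plasma cell-like cells has the values it needs: the ratio of Igkc to Igha departed by at most 1.41-fold from that of plasma cell-like cells over 11 classes. Doublets with plasma cell-like cells are argued against, because the top 5% of KO NK cell-like cells held only 32.2% of these UMIs. No biological explanation was tested.

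The third pattern was the rise of type I interferon response genes in lung Ly6C-high monocyte-like cells (median 0.661). The depth gap is argued against, with a median of 0.487 when every cell was thinned to 2000 UMIs (camera adjusted p = 2.51e-11, and adjusted p = 0.222 with an estimated correlation). A different mix of clusters is argued against by cluster 3 alone (0.63) and left open by cluster 8 alone (0.329). Free RNA is argued against for the 13 of 29 list members tested in NK cell-like cells, with a median of -0.122 there (quartiles -0.334 to 0.081) against 0.636 in the monocyte-like cells. It is left open for the other 16, whose median in NK cell-like cells without a low-count filter was 0.445 (quartiles -0.155 to 0.824) against 0.734. Their sum was 45.2 ± 2.79 CPM in WT and 52.7 ± 4.24 CPM in KO NK cell-like cells (SD, n = 3). Genotype and library remain joined, so loss of NRF2 cannot be told apart from another difference between the 2 lung libraries.

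The pools of each tissue allow only 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of 10, gave the most genes each time: 1734 against at most 0 in other splits for all marrow cells, 3983 against 0 for all lung cells, 290 against 1 for GMP-like, 1235 against 0 and 850 against 0 for marrow and lung Ly6C-high monocyte-like, 59 against 1 for monocyte-derived macrophage-like and 732 against 0 for alveolar macrophage-like cells. The other classes gave 1875 against 105, the gene lists 79 against 65, and lung shares 8 against 0. For marrow shares all 10 splits gave 0. Within single comparisons, another split called more lists than the real one in marrow: 12 against the real 7 for all cells, 9 against 8 in GMP-like and 12 against 11 in Ly6C-high monocyte-like cells, so the marrow list counts do not stand out. In lung the real split called the most: 12 against 11 for all cells, 13 against 11 in Ly6C-high monocyte-like, 13 against 11 in monocyte-derived macrophage-like and 15 against 10 in alveolar macrophage-like cells. Splits that mixed the genotypes thus reached 10 to 11 lists in lung. The number of lists called by camera with the preset correlation is therefore little evidence in either tissue.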

How the results depend on the processing

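Thinning, removal of genes called outside the lineage, the total without NK cell-like cells and clustering without called genes were chosen after results were seen. Of 487 named genes that passed with edgeR, RLE normalization kept 485 and DESeq2 432, with 35 lost and 20 given no adjusted p. Of 467 such genes outside the interaction, 136, 134 and 113 no longer passed without KO replicate 1, 2 or 3, and 75, 44 and 100 without WT replicate 1, 2 or 3. Thinned cells kept 183 of 270, and resolution 2 kept 267 of 303, with 1 reversed: Mpo in marrow Ly6C-high monocyte-like cells, at -0.0281. Leave-one-out gave 56 (without WT replicate 3) to 2942 (without WT replicate 2) genes for all marrow cells, 2956 to 3716 for all lung cells, 78 to 460 for GMP-like, 205 to 2002 for marrow Ly6C-high monocyte-like, 434 to 765 for lung Ly6C-high monocyte-like, 26 to 141 for monocyte-derived macrophage-like and 401 to 878 for alveolar macrophage-like cells. It gave 821 to 2328 for other classes, 41 to 161 for the interaction, 71 to 83 lists and 6 to 9 lung shares. Fewer pools lower the power, and the cause of the higher counts was not tested. Without a low-count filter the counts were 556 (GMP-like), 1857 and 435 (marrow Ly6C-high monocyte-like and monocyte-derived macrophage-like), 1328 (alveolar macrophage-like), 4020 (other classes) and 266 (interaction). DESeq2 gave 474 in lung Ly6C-high monocyte-like cells, 92 in monocyte-derived macrophage-like cells and 119 for the interaction. Thinned cells gave 39, 444, 358 and 197 for GMP-like, marrow and lung Ly6C-high monocyte-like and alveolar macrophage-like cells, since fewer UMIs and genes were tested. The stricter cell filter gave 383 in alveolar macrophage-like cells, and resolution 2 gave 22 in monocyte-derived macrophage-like cells. The cause was not tested. Without genes also called outside the lineage, 222 GMP-like, 1107 marrow and 820 lung Ly6C-high monocyte-like, 48 monocyte-derived and 704 alveolar macrophage-like calls were left. With pool number as a block, which does not pair these samples, 1266 genes passed for all marrow cells and 88 in monocyte-derived macrophage-like cells. Of 79 lists called with camera, 0 were called with an estimated correlation and 24 with fry, which called 28 in all. In monocyte-derived macrophage-like cells the MHC class I list ranged from an adjusted p of 3.14e-09 to 0.808 (camera, leave-one-out), reversed without KO replicate 1, and the neutrophil RNA list from 0.000527 to 0.742, reversed without KO replicate 3 (0.7). The share of monocyte-derived macrophage-like cells passed in every setting (-1.37 to -2.02), and with neutrophil-like and non-myeloid classes left out 5 lung classes passed. The Ms4a3 change over all marrow cells ranged from -1.59 to -1.13. Lung KO cells were shallower, which limits the genes that can be tested there.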

Other observations

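The list tests of other classes, the score differences for interferon and MHC lists and the list tests of the interaction were chosen after results were seen. A marrow cluster led by Ccl5, Gzma and Xcl1, genes of cytotoxic lymphocytes, had higher cell cycle transcripts in KO, with 16 of 25 genes rising (median log2 change 1.13, camera adjusted p = 7.78e-27, and adjusted p = 0.12 with an estimated correlation). Granule protein genes rose with them (4 of 11, median 0.909, adjusted p = 2.93e-10, and adjusted p = 0.12 with an estimated correlation), as did 4 of 6 neutrophil RNA markers (median 1.47, adjusted p = 1.99e-13, and adjusted p = 0.14 with an estimated correlation), and 6.456% of the cells of this cluster before removal were doublet calls. In the lung cluster led by Ccl24, Ccl12 and Ccl2, whose share was lower in KO, 4 of 28 type I interferon response genes rose (median 0.662, adjusted p = 1.65e-16, and adjusted p = 0.257 with an estimated correlation), and 2 of 9 MHC class II genes (median 0.518, adjusted p = 2.87e-08, and adjusted p = 0.309 with an estimated correlation). In cDC2-like cells 3 of 19 tumour macrophage genes fell (median -0.518, adjusted p = 0.0001, and adjusted p = 0.357 with an estimated correlation).

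Oxidative phosphorylation genes were also lower in HSPC-like cells (median -0.236, camera adjusted p = 2.35e-10, and adjusted p = 0.31 with an estimated correlation) and in immature neutrophil-like cells (median -0.16, adjusted p = 2.8e-08, and adjusted p = 0.269 with an estimated correlation). Ribosomal protein genes such as Rpl27 (-0.346) and Rps18 (-0.339) fell in HSPC-like cells too, while mt-Nd3 rose (0.972). HSPC-like cells hold cells that precede the GMP, though Ms4a3 was found in them at 349 ± 123 CPM in WT pools, so where the Cre acts was not settled.

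The interferon score of lung Ly6C-high monocyte-like cells minus that of alveolar macrophage-like cells went from 2.16 ± 0.29 in WT to 3.18 ± 0.35 in KO, a difference of 1.02 (exact permutation p = 0.1). For monocyte-derived macrophage-like cells it went from 0.68 ± 0.22 to 1.46 ± 0.20 (0.78, exact permutation p = 0.1). In the interaction between tissues the type I interferon list had a median of 0.50, higher in lung (camera adjusted p = 6.07e-08, and adjusted p = 0.399 with an estimated correlation), with 1 member called. Technical lists moved in the same test: the mitochondrial list was lower in lung (median -0.231, adjusted p = 2.36e-16, and adjusted p = 0.0693 with an estimated correlation), as was the neutrophil RNA list (median -4.87, adjusted p = 0.00446, and adjusted p = 0.399 with an estimated correlation).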
